A study of Homo sapiens with 6 samples.

How the data were processed

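Libraries of mRNA from 6 samples labelled HCT8 were prepared with Illumina protocols, per the labels' protocols, from total RNA extracted with Trizol. The cells were transfected with a control plasmid in 3 samples and with a GPT1 overexpression plasmid in 3 samples. The deposited values are raw read counts per gene, whole numbers that the authors made per sample. Reads were aligned with HISAT2 2.0 to the GRCh38 genome, per the submitters' processing notes. The counting tool, its annotation release and its strand setting are not given in the sources used here, so reads that overlapping genes or close paralogs share cannot be assigned with certainty. The table held 60664 Ensembl gene identifiers and 6 columns, each matched to a sample by its name. Gene symbols came from a GENCODE 29 name table, which matched 60463 identifiers and left 201 without a symbol, and coordinates are those of GENCODE 29 on GRCh38.

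Total counts ranged from 21255655 (control replicate 3) to 32487217 (control replicate 1), and the 10 most abundant genes took 4.71% to 5.62% of the counts. Before groups were averaged, replicate pairs were compared over genes with at least 20 counts. The chi-square per degree of freedom lay between 9.98 and 30.8, far above sampling noise, so that all 6 libraries counted as separate samples. No source states that they came from separate cultures. The p-values then measure only the spread between these samples, which may be technical.

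Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (17638), library sizes were scaled with TMM factors, and groups were compared with the quasi-likelihood F test (glmQLFit, glmQLFTest; two-sided) with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. CPM values of single genes use TMM-scaled library sizes, and CPM sums over marker lists use the total counts of each library without TMM factors. Standard errors of log2 fold changes were derived from the fitted value and its F statistic. The common biological coefficient of variation was 0.119. The GPT fold change was also given as a ratio of counts with an exact 95% interval and an exact permutation test of CPM.

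Before the data were examined, 38 gene lists with 976 genes were fixed, and 1 gene of these had no match in the table. They covered amino acid, glucose, one-carbon, lipid and mitochondrial metabolism, signalling targets, stress responses, cell cycle and death, immune genes, epithelial and intestinal differentiation, ribosomes and histones, and markers of other cell types. The 34 lists with at least 5 measured members were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 34 lists. Camera with a correlation estimated per list and fry were run beside it. For the lists of alanine, glutamate, aspartate and proline enzymes, of glycolysis, of the citric acid cycle and of the BCL2 family, the median, the mean and the direction of the test differed in sign. None of these 4 lists was called.

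The rule for named genes was fixed at the same time. It took GPT and GPT2, the 10 genes per direction with the largest absolute log2 fold change among those past the threshold with a mean of at least 5 CPM, groups that do not overlap and a symbol that is not a clone name, and up to 4 members with the smallest adjusted p in each tested list. Other genes were named after their values were seen. EPCAM, VIM, KRT8, KRT18, CDX2, PAX2, LRRC14, PPP1R16A, ENSG00000255182 and the members PRDX1, TXN, FTH1, GCLM, AKR1C3, CMPK2, EPSTI1, IFI6, OAS3, MX1, BAK1, HRK, BBC3, CASP8, BCL2, NIT2, GLS2, ABAT, PPAT, MTR, MTRR, FOLR1, EGLN2, JMJD6, AURKA, KIF2C, UBE2C, HSPA4L, BIRC5, STC2, SPARC, GADD45A, NFKBIA, NFKB1, ITGAX and SERPINA1 are such genes, as are RHOB, PLAT, IRS4, FAT1, SRSF3, RBM3, HNRNPM and ATP6V0B. Some genes that the rule took or that were looked up later are not reported here.

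Alternatives planned beforehand were other scaling factors, GPT left out, other expression filters, DESeq2 1.42.0, limma voom, a test against a 1.2-fold change (glmTreat), an adjusted p of 0.01, the replicate number as a block, each library left out in turn, and other forms of camera. A correction for transcript length and GC content was added after the data were seen. It fitted a smooth function (mgcv 1.9.3) of the length and GC content of each gene's longest GENCODE 29 transcript to each library's log2 deviations and used the fit as an offset. Of the tested genes, 98.9% had both values.

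The gene test, camera and the correction were tested on simulated data for the comparison of GPT1 overexpression with control, drawn from the real means, dispersions and library sizes with 200 changed genes. Among 17369 simulated genes tested, the edgeR test recovered 52.2% of genes changed 1.5-fold, 97.0% of those changed 2-fold and 100% of those changed 4-fold, and called 0.0874% of unchanged genes. With the length and GC trends of the real libraries added to the simulation (17386 genes tested), the uncorrected test recovered 32.8%, 86.6% and 100% and called 0.291% of unchanged genes. The corrected test recovered 52.2%, 95.5% and 100%. Camera called the changed list and 0 of the other 33 lists in each of these simulations. Genes were drawn independently of each other and the other lists at random. The simulations therefore do not test camera on lists whose members are correlated or share a transcript length. Changed genes were drawn only from genes above a minimum mean count, so recovery at low counts was not tested. Far fewer genes changed than passed in the real comparison. The adjusted threshold was therefore stricter in the simulations, and the shares recovered do not carry over to that comparison.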

Results

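mRNA was sequenced from 6 libraries of cells labelled HCT8, a human colorectal cancer line grown in culture. 3 libraries came from cells transfected with a control plasmid and 3 from cells transfected with a plasmid that overexpresses GPT1. GPT1, with the gene symbol GPT, is the cytosolic alanine aminotransferase, the enzyme that converts alanine and alpha-ketoglutarate to pyruvate and glutamate. GPT2 encodes its mitochondrial counterpart. The stated question of the series was which signalling pathway GPT1 regulates in colorectal cancer. The deposited counts summed to 32487217, 31876838 and 21255655 in the control libraries, replicate 3 being the shallowest. The GPT1 libraries held 31513656, 30370654 and 30796222 counts. Of 60664 genes in the table, 31515 had a count in any library and 17638 were tested.

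GPT transcripts were at the floor in the control libraries and abundant in the GPT1 libraries. GPT (ENSG00000167701, GRCh38 chromosome 8, 144502973 to 144507174, plus strand, protein-coding) had 9, 14 and 3 counts in the controls and 105529, 96886 and 106063 counts in the GPT1 libraries. As CPM, the count scaled to library size, this was 0.286 ± 0.153 against 3347 ± 152 (SD, n = 3 per group), and it made up 0.335%, 0.319% and 0.344% of all counts in the GPT1 libraries. The log2 fold change was 13.42 ± 0.19 (SE; adjusted p = 1.2e-11, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The ratio of the summed counts, scaled by library totals, was 10961, with an exact 95% interval of 7480 to 16779 that covers counting error only. An exact two-sided permutation test of the CPM values gave p = 0.1, the smallest that 3 against 3 libraries allow. The counts do not separate plasmid from endogenous transcripts. GPT2 (chromosome 16, 46884378 to 46931297, plus strand) stood at 243 ± 27.4 CPM in the controls and 283 ± 18.9 CPM in the GPT1 libraries (log2 fold change 0.22 ± 0.10, adjusted p = 0.121, edgeR), so that its transcript was the abundant form in the controls. ENSG00000255182, a processed transcript on the minus strand (144495458 to 144505444) that overlaps GPT, rose from 7.04 ± 0.69 to 19.7 ± 3.90 CPM. The strand setting of the counting is not given in the sources used here, so its reads and those of GPT cannot be told apart. The nearby gene LRRC14 (144517992 to 144525178, plus strand) also rose, from 75.5 ± 7.07 to 113 ± 6.34 CPM, whereas PPP1R16A, directly upstream of GPT, stood at 38.3 ± 3.78 and 38.4 ± 2.77 CPM.

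**Figure D1:**
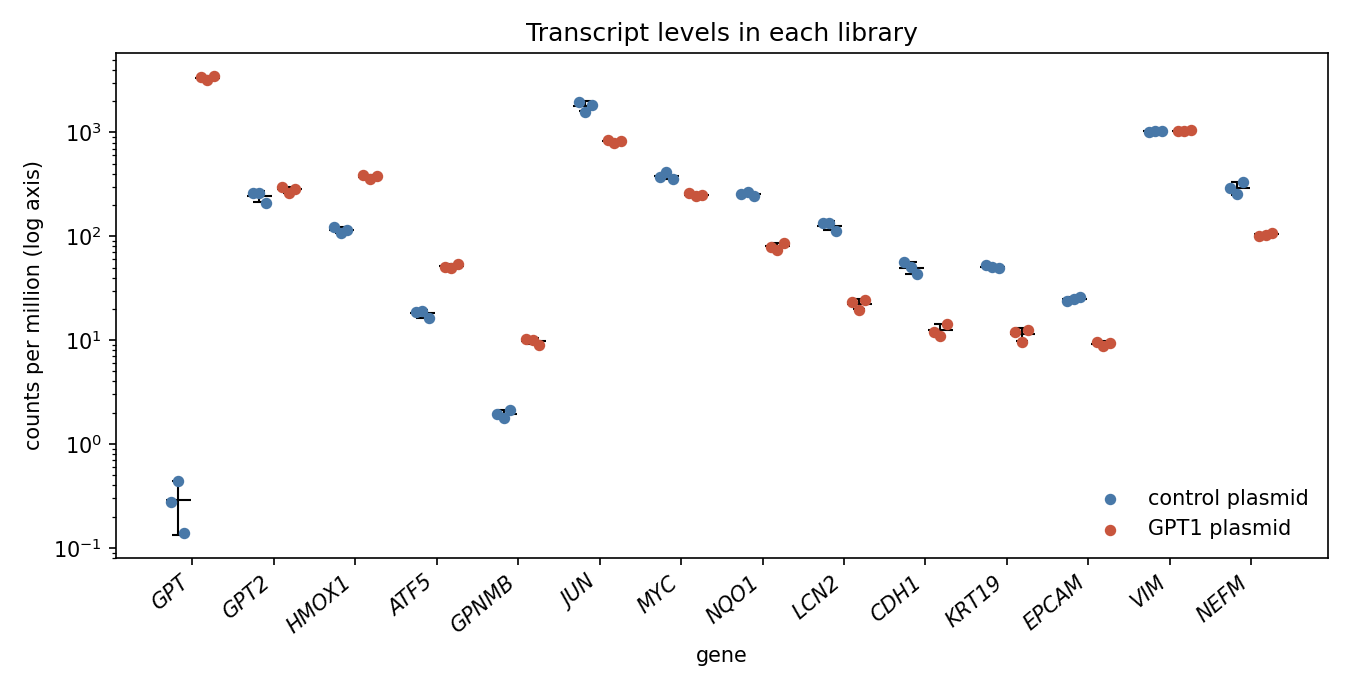
CPM on a log axis for 14 genes in each of the 6 libraries, with points for libraries and black bars for the group mean and SD (n = 3 per group). GPT rose from 0.286 to 3347 CPM, HMOX1, ATF5 and GPNMB rose, JUN, MYC, NQO1, LCN2, CDH1, KRT19, EPCAM and NEFM fell, and VIM stood at 1023 and 1039.7 CPM.

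To find what else differed with GPT1 overexpression, the 3 GPT1 libraries were compared with the 3 control libraries gene by gene. The genes that fell furthest included LCN2, a secreted siderophore-binding protein that went from 127 ± 12.4 to 22.3 ± 2.52 CPM, KRT19, a simple-epithelium keratin that went from 51.2 ± 1.99 to 11.4 ± 1.65 CPM, and the tight-junction gene CLDN4. The genes that rose furthest included HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1 (115 ± 7.60 to 374 ± 19.0 CPM), ATF5, a stress-responsive transcription factor (18.1 ± 1.56 to 51.8 ± 2.51 CPM), and the melanosomal and lysosomal glycoprotein gene GPNMB (1.94 ± 0.18 to 9.84 ± 0.69 CPM). In all, 4430 of 17638 genes (25.1%) passed an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), of which 1858 were higher and 2572 lower in the GPT1 libraries. Most changes were modest, with a median absolute log2 fold change of 0.60 among the called genes. 888 genes changed at least 2-fold, 293 of them higher and 595 lower. In 43.4% of the tested genes the libraries of one group all lay above those of the other, against 10% by chance. Genes are not independent, and a trend across a library's genes that differs between the groups would raise this share too.

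The 10 genes with the largest falls at a mean of at least 5 CPM had log2 fold changes from -2.77 to -2.17, each past the threshold in the edgeR test. These were IGFBP3 (-2.77 ± 0.36 SE), a binding protein of insulin-like growth factors, LCN2 (-2.51 ± 0.12), the secreted serine protease genes KLK10 (-2.32 ± 0.15) and KLK6 (-2.17 ± 0.16), EREG (-2.32 ± 0.14), a ligand of the EGF receptor, and DUSP6 (-2.32 ± 0.20), a phosphatase of ERK. GPX2 (-2.30 ± 0.14), the gastrointestinal glutathione peroxidase, CLDN4 (-2.27 ± 0.12), the growth factor gene FGF19 (-2.20 ± 0.18) and KRT19 (-2.17 ± 0.13) completed them. GPT aside, the 10 largest rises at that level were smaller, from 2.37 to 1.29. They comprised DNAH17 (2.37 ± 0.17), an axonemal dynein heavy chain, GPNMB (2.35 ± 0.15), the cancer-testis antigen gene MAGEC2 (2.25 ± 0.16), HMOX1 (1.70 ± 0.08), CCN3 (1.61 ± 0.13), which encodes a matricellular protein, and ATF5 (1.52 ± 0.11). HLA-DRB1 (1.51 ± 0.13), a chain of MHC class II, ELSPBP1 (1.46 ± 0.18), C1orf53 (1.43 ± 0.20) and the keratin-associated protein gene KRTAP19-1 (1.29 ± 0.11) followed. Reads of HLA-DRB1, MAGEC2 and KRTAP19-1 can be shared with close paralogs, so their levels are uncertain.

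The libraries also differed by GC content and length of the transcripts, across genes of both groups. The log2 fold change correlated across 13466 genes with transcript length (Spearman -0.39) and with GC content (0.39), genes not being independent replicates. Libraries of one group differed in this too, since the deviation of control replicate 3 correlated with GC content at -0.62 and those of control replicates 1 and 2 at -0.05 and 0.10. After correction of each library for both trends, an alternative added after the data were seen, 3286 genes were higher and 2777 lower, beside the 1858 and 2572 without it. Leaving out control replicate 1, GPT1 replicate 1 or GPT1 replicate 3 lowered the number of changed genes to 2565, 1586 and 1443.

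**Figure D2:**
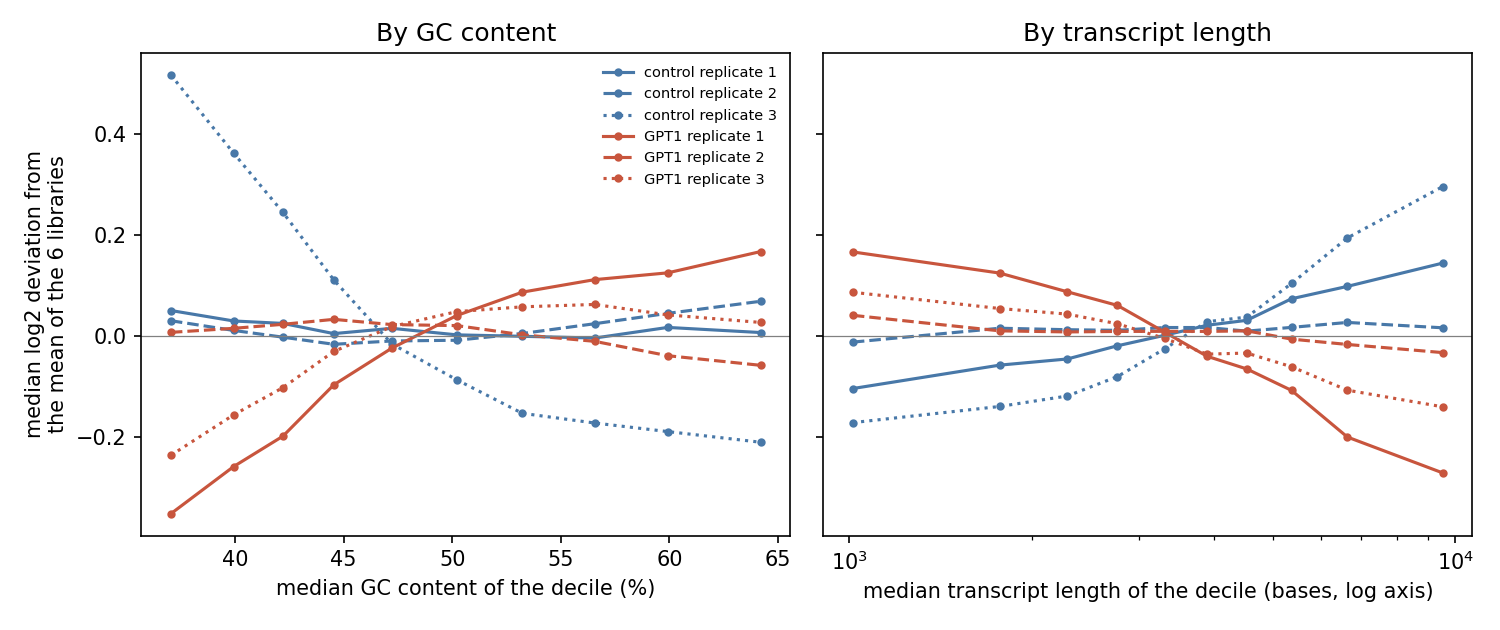
Median log2 deviation of each library from the mean of the 6 libraries, for genes in 10 equal groups by GC content (left, in %) or transcript length (right, in bases on a log axis), with 1 line per library. In the group of lowest GC content, control replicate 3 stood at 0.52 and GPT1 replicate 1 at -0.35, whereas control replicates 1 and 2 stood at 0.05 and 0.03.

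Genes of epithelial junctions and intestinal differentiation were lower in the GPT1 libraries. CDH1, which encodes E-cadherin, went from 50.1 ± 6.26 to 12.5 ± 1.74 CPM, and the epithelial adhesion gene EPCAM from 24.9 ± 1.15 to 9.28 ± 0.44 CPM. The claudin gene CLDN3 (log2 fold change -2.58 ± 0.21 SE), the microvillus gene VIL1 (-1.96 ± 0.14), the intestinal lectin gene LGALS4 (-2.26 ± 0.19) and AGR2 (-2.25 ± 0.21), a protein disulfide isomerase of mucus-secreting cells, fell as well. The keratin genes KRT8 and KRT18 fell less, from 529 ± 45.3 to 352 ± 19.3 CPM and from 261 ± 25.8 to 171 ± 12.6 CPM. CDX2, an intestinal transcription factor, stood at 41.7 ± 4.47 and 45.3 ± 3.56 CPM (adjusted p = 0.448, edgeR). Of 28 measured genes of the epithelial junction and keratin list, 18 fell and 10 did not pass, and 22 fell when p was adjusted over the list alone. The list's median log2 fold change was -0.68 (camera with a preset correlation of 0.01, adjusted p = 5.7e-09 over 34 lists; adjusted p = 0.140 with an estimated correlation). In the enterocyte list 8 of 14 measured genes fell, and 8 adjusted over the list alone (median -0.74, camera adjusted p = 0.00015; adjusted p = 0.147 with an estimated correlation). In the goblet and secretory list 4 of 9 fell, namely AGR2, KLK6, DLL4 and the barely detected MUC5AC, and 5 adjusted over the list alone (median -0.33, and -0.76 without GPT1 replicate 1; camera adjusted p = 0.0089; adjusted p = 0.233 with an estimated correlation). MUC5AC did not pass without control replicate 1 or GPT1 replicate 3 (edgeR adjusted p up to 0.0615), nor DLL4 without control replicate 2, GPT1 replicate 2 or GPT1 replicate 3 (up to 0.0706).

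Some markers of other cell types moved with the groups too. The neurofilament genes NEFM and NEFL were abundant in both groups and fell, from 293 ± 41.7 to 104 ± 3.33 CPM and from 152 ± 4.61 to 83.0 ± 0.43 CPM, as did MAP2 (log2 fold change -1.35 ± 0.18 SE), which encodes a neuronal microtubule protein. These were the 3 of 9 measured genes that passed in a list of neural and kidney-line markers, and 3 passed adjusted over the list alone (median -0.38, camera adjusted p = 0.0352; adjusted p = 0.313 with an estimated correlation). The list's call ended without control replicate 1, control replicate 2 or GPT1 replicate 2 (camera adjusted p = 0.0848, 0.0986 and 0.0766), with a median of -0.17 without control replicate 2. The kidney-lineage gene PAX2 (5.65 ± 0.52 and 5.14 ± 0.81 CPM) differed by no more than the spread between replicates. VIM, the intermediate filament gene of mesenchymal cells, stood at 1023 ± 14.6 and 1039.7 ± 4.68 CPM. In a fibroblast list COL6A3 (1.46 ± 0.15), ACTA2 (0.49 ± 0.10, and 0.30 after the length and GC correction) and LUM (0.80 ± 0.25) rose out of 11 measured, all 3 also adjusted over the list alone, without a call for the list (median 0.00, camera adjusted p = 0.304). Summed over all members, the epithelial junction and keratin list held 1801 ± 45.0 CPM in the controls and 1264 ± 41.2 CPM in the GPT1 libraries, and the neural and kidney-line list held 516 ± 47.1 and 249 ± 1.15 CPM. KRT8 and KRT18, which fell less than CDH1 and EPCAM, made up much of the epithelial sum. Without NEFM and NEFL the neural and kidney-line sum was 69.4 and 63.1 CPM. The fibroblast list held 586 ± 45.1 and 590 ± 24.4 CPM. Endothelial and leukocyte lists, with 2 and 4 measured genes, and a hepatocyte list with 3 were too short to test, the leukocyte integrin gene ITGAX (-0.98) and the hepatocyte gene SERPINA1 (-2.29) being the genes that fell in them. No erythroid gene was measured. Without control replicate 1, GPT1 replicate 1 or GPT1 replicate 3, ITGAX did not pass (edgeR adjusted p up to 0.0718). The same held for LUM (0.138), also without control replicate 2.

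Growth-factor and Wnt response genes fell in the GPT1 libraries, in which the summed epithelial markers stood at 1264 against 1801 CPM. KRT8 and KRT18 made up much of that sum, with log2 fold changes of -0.59 and -0.61, so the sum understates the falls of other epithelial genes. JUN, a subunit of the AP-1 transcription factor, went from 1798 ± 198 to 820.4 ± 20.6 CPM, and MYC from 381 ± 26.9 to 251 ± 9.27 CPM. EREG and AREG (-2.16 ± 0.16), both ligands of the EGF receptor, and DUSP6 and PHLDA1 (-1.64 ± 0.14), both induced by ERK signalling, fell by larger factors. Falls of similar size occurred among epithelial and intestinal genes, of which 19 fell by over 1.5 on the log2 scale, with a median of -2.08. Of 32 measured genes of the ERK and AP-1 immediate response list, 19 fell and 13 did not pass (median log2 fold change -0.61, camera adjusted p = 2.1e-08; adjusted p = 0.147 with an estimated correlation), and 23 passed adjusted over the list alone. In the list of Wnt/beta-catenin targets 17 of 29 fell, among them AXIN2 (-0.95 ± 0.14), a feedback inhibitor of the pathway, LGR5 (-0.93 ± 0.17) and SOX9 (-1.23 ± 0.12), and BIRC5 (0.47) rose. This list's median was -0.54 (camera adjusted p = 7.7e-07; adjusted p = 0.233 with an estimated correlation), and 20 genes passed adjusted over the list alone. AXIN2, LGR5 and SOX9 also belong to the intestinal stem cell list, in which 6 of 18 fell, and 7 adjusted over the list alone (median -0.38, and -0.21 after the length and GC correction; camera adjusted p = 0.0330; adjusted p = 0.233 with an estimated correlation). That call ended without control replicate 2 or GPT1 replicate 2 (camera adjusted p = 0.0535 and 0.0554). JUN and MYC belong to both the Wnt and the ERK lists.

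Hypoxia-inducible factor targets were lower as well. SLC2A1, the glucose transporter GLUT1, went from 129 ± 17.4 to 73.9 ± 5.90 CPM, P4HA1, a collagen prolyl hydroxylase, from 51.6 ± 11.5 to 25.1 ± 1.36 CPM, and NDRG1 from 155 ± 43.6 to 70.8 ± 4.66 CPM. Of 26 measured genes of the list, 17 fell and STC2 rose (0.32), with 21 past the threshold adjusted over the list alone (median -0.40, camera adjusted p = 2.4e-05; adjusted p = 0.415 with an estimated correlation). The matrix gene THBS1 (log2 fold change -0.90 ± 0.14 SE) was among 8 of 19 TGF-beta targets that fell, and 9 passed adjusted over the list alone (median -0.26, and -0.15 after the length and GC correction; camera adjusted p = 0.0161; adjusted p = 0.415 with an estimated correlation). Of 21 mesenchymal and invasion genes 7 fell, among them the fibronectin gene FN1 (-1.02 ± 0.10) and the transcription factor gene SNAI2 (-0.54 ± 0.10), SPARC (1.01) rose, and 9 passed adjusted over the list alone (median -0.32, camera adjusted p = 0.0089; adjusted p = 0.250 with an estimated correlation). Of 19 NF-kB and inflammatory targets 8 fell, including ICAM1 (-1.74 ± 0.19), BIRC3 (-2.51 ± 0.43) and IL32 (-1.09 ± 0.14), NFKBIA (0.41, and 0.23 after the length and GC correction) and NFKB1 (0.37) rose, and 11 passed adjusted over the list alone (median -0.28, camera adjusted p = 0.0330; adjusted p = 0.415 with an estimated correlation). The NF-kB call ended without control replicate 2 or GPT1 replicate 2 (camera adjusted p = 0.102 and 0.0514), and that of the TGF-beta targets without GPT1 replicate 2 (0.0554). The NF-kB median was -0.45, -0.16 and -0.42 without control replicates 1, 2 and 3. Without GPT1 replicate 1 or 3, STC2 and NFKB1 did not pass (edgeR adjusted p up to 0.108 and 0.0999; 0.0560 and 0.0511 with the replicate number as a block). The same held for SPARC and NFKBIA (0.0626 and 0.0994), also without control replicate 1. LCN2 also belongs to the NF-kB list, and the summed neural and kidney-line markers (249 against 516 CPM) were lower in the same libraries. That fall came mostly from NEFM and NEFL, without which the sum was 63.1 against 69.4 CPM.

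Lists that rose included 3 made up of short transcripts, in libraries that also differed in the summed epithelial markers (1264 against 1801 CPM). Nuclear genes of oxidative phosphorylation rose by small amounts, such as the complex I genes NDUFA1 (49.0 ± 1.38 to 88.0 ± 7.78 CPM) and NDUFB3 (29.6 ± 2.49 to 48.1 ± 2.39 CPM) and the complex IV gene COX7C (141 ± 4.54 to 221 ± 11 CPM). Of 44 measured, 25 rose and 19 did not pass, with 26 adjusted over the list alone (median 0.33, camera adjusted p = 5.7e-09; adjusted p = 0.368 with an estimated correlation). Of the 13 protein-coding genes of the mitochondrial genome, 0 passed the edgeR test, with 1 at an unadjusted p under 0.05, 1 past DESeq2's and 0 past limma voom's threshold (median -0.26, camera adjusted p = 0.378; -0.50 and adjusted p = 0.0372 without GPT1 replicate 2). Without control replicate 3 the median was -0.17 (camera adjusted p = 0.445). Of 58 cytosolic ribosomal protein genes 12 rose, among them RPS12 (0.74 ± 0.09) and RPLP1 (0.71 ± 0.10), and 12 adjusted over the list alone (median 0.15, and 0.086 without GPT1 replicate 1; camera adjusted p = 3.6e-05; adjusted p = 0.629 with an estimated correlation). The call ended after the length and GC correction (median 0.084, camera adjusted p = 0.124). Of 20 replication-dependent histone genes 11 rose, among them H2BC12 (1.04 ± 0.09) and H1-2 (0.77 ± 0.15), and 11 adjusted over the list alone (median 0.61, camera adjusted p = 2.4e-05; adjusted p = 0.233 with an estimated correlation). Ribosomal protein and histone genes share sequence with pseudogenes or copies, so single members are uncertain. Their median transcript lengths were 1912, 1864.5 and 754 bases for the oxidative phosphorylation, ribosomal and histone lists, and genes of shorter transcripts were higher in the GPT1 libraries in general. With the correction for length and GC content the call of the ribosomal list ended (median 0.08, camera adjusted p = 0.124).

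p53 targets rose as a list, in libraries that also differed in the summed epithelial (1264 against 1801 CPM) and neural and kidney-line markers (249 against 516 CPM). Without NEFM and NEFL the neural and kidney-line sum was 63.1 against 69.4 CPM. CDKN1A, the p21 inhibitor of the cell cycle, went from 167 ± 19.7 to 270 ± 25.04 CPM, BAX, a pro-apoptotic pore protein, from 116 ± 15.7 to 191 ± 15.4 CPM, and TP53I3 from 20.7 ± 2.36 to 36.4 ± 2.26 CPM. Of 29 measured, 12 rose, GADD45A fell (-0.28, and -0.47 after the length and GC correction) and 16 did not pass, with 13 adjusted over the list alone (median 0.16, camera adjusted p = 0.0057; adjusted p = 0.233 with an estimated correlation). After the length and GC correction the median was 0.40, with 15 higher and 3 lower. In the BCL2 family and cell death list 11 of 25 changed without a common direction, and 12 adjusted over the list alone (camera adjusted p = 0.622). BAX, BAK1, HRK, BBC3 and CASP8 rose there, and PMAIP1 (-0.92 ± 0.11), the BH3-only gene that encodes NOXA, BIK (-1.53 ± 0.16) and BCL2 (-0.42; -0.22 and adjusted p = 0.0805 after the length and GC correction) were among the 6 that fell. Without control replicate 1, GPT1 replicate 1 or GPT1 replicate 3, BCL2, BAK1 and CASP8 did not pass (edgeR adjusted p up to 0.144, 0.134 and 0.127). The same held for GADD45A (0.106), also without GPT1 replicate 2. BBC3 did not pass without GPT1 replicate 1 (0.0665), nor HRK without GPT1 replicate 3 (0.0587). With the replicate number as a block GADD45A, BCL2 and CASP8 did not pass (0.0730, 0.0651 and 0.0687).

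**Figure D3:**
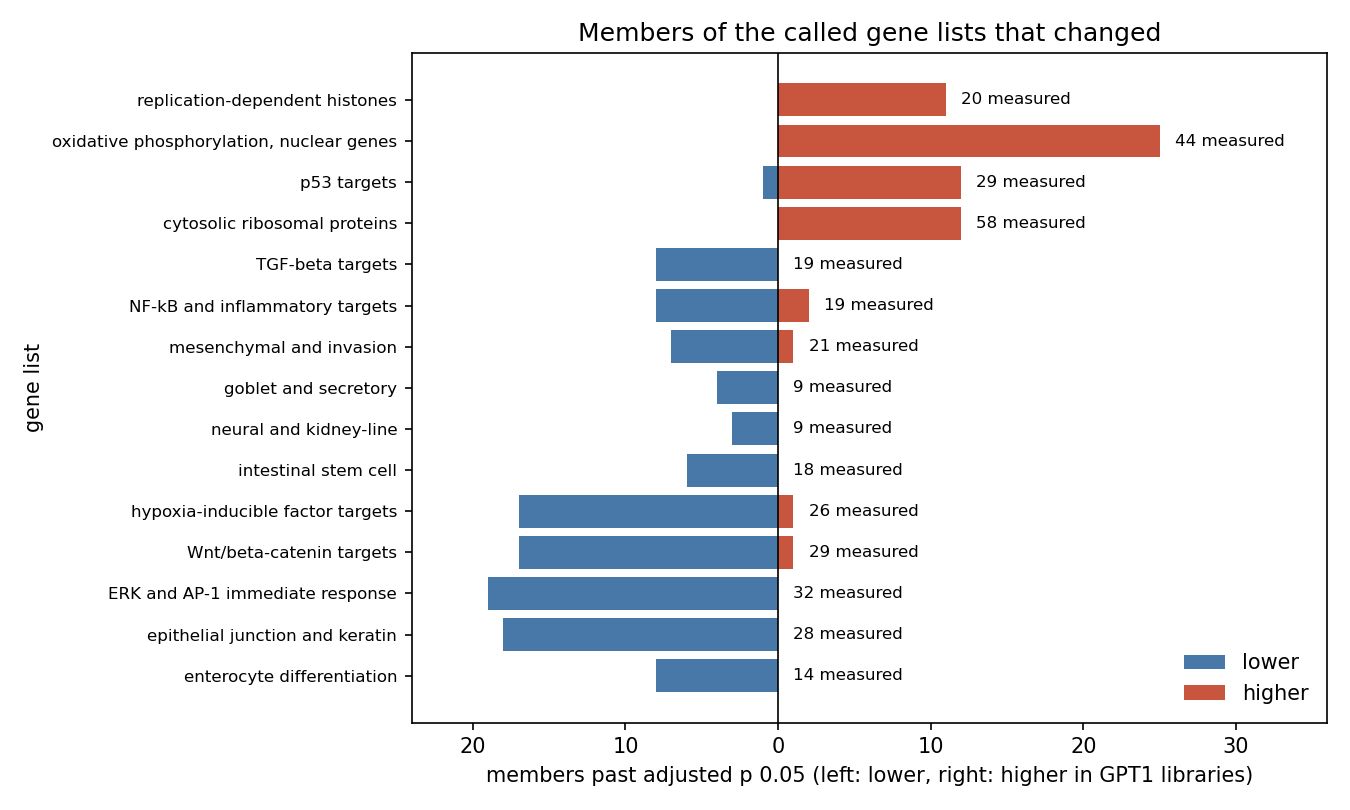
Number of genes past an adjusted p of 0.05 in each of the 15 lists called by camera with a preset correlation, drawn to the left where lower and to the right where higher in the GPT1 libraries, with the number measured beside each bar. 19 of 32 ERK and AP-1 genes were lower, and 25 of 44 nuclear oxidative phosphorylation genes were higher.

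Lists of amino acid metabolism were not called by camera. The enzyme list was tested with the transfected gene GPT in it, with a mean log2 fold change of 0.42 and a median of -0.01. With GPT left out it was not called either, whereas fry with GPT in the list called it (adjusted p = 0.0102). Beside GPT itself, ADSL (0.45 ± 0.12) and NIT2 (0.32, and 0.67 after the length and GC correction) rose among 27 measured enzymes of alanine, glutamate, aspartate and proline, and the asparagine synthetase gene ASNS (-1.10 ± 0.23), the argininosuccinate synthase gene ASS1 (-0.36 ± 0.08), GLS2, ABAT and PPAT fell, PPAT no longer after that correction (0.00), the same number adjusted over the list alone (8; camera adjusted p = 0.623). Among ATF4 and amino acid response genes 8 of 36 rose, ATF5 by most, and 5 fell, including DDIT4 (-0.84 ± 0.11), ASNS and ALDH1L2, with 15 adjusted over the list alone (camera adjusted p = 0.197). In the folate and one-carbon list 8 of 34 rose, among them the thymidylate synthase gene TYMS (0.55 ± 0.10) and the S-adenosylmethionine synthase gene MAT2A (0.70 ± 0.08). MTR, MTRR, ALDH1L1, ALDH1L2 and FOLR1 fell, with 13 adjusted over the list alone (camera adjusted p = 0.135). After the correction MTR (-0.39) no longer passed (-0.12, adjusted p = 0.106), and MTRR (-0.34) and ALDH1L2 (-0.55) fell by less (-0.21 and -0.24). Of 33 alpha-ketoglutarate-dependent dioxygenases 7 fell and EGLN2, HIF1AN (0.41, and 0.65 after the correction) and JMJD6 rose, with 12 adjusted over the list alone (camera adjusted p = 0.460). Without control replicate 1, GPT1 replicate 1 or GPT1 replicate 3, ADSL, PPAT and MTR did not pass (edgeR adjusted p up to 0.0745, 0.114 and 0.103). The same held for NIT2 (0.155), also without control replicate 2, and for ABAT (0.189), also without GPT1 replicate 2. It held for GLS2 (0.114), also without control replicate 2 or GPT1 replicate 2, and for MTRR (0.180), also without control replicate 2 or 3. ASS1 did not pass without control replicate 1 or GPT1 replicate 3 (up to 0.0640), nor did FOLR1 without control replicates 1 or 2 or GPT1 replicates 2 or 3 (0.110). EGLN2 did not pass without control replicate 1 or GPT1 replicates 1 or 2 (0.0976), nor did JMJD6 without GPT1 replicates 1 or 3 (0.0920) or HIF1AN without GPT1 replicate 3 (0.0521). ABAT also did not pass with RLE or upper quartile factors, without a filter, with DESeq2 or with the replicate number as a block (0.0546 to 0.101). GLS2 and MTRR did not pass with upper quartile factors (0.0509 and 0.0602), nor did NIT2 and MTRR with the block (0.0781 and 0.0892).

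NRF2 targets moved in both directions, in libraries that also differed in the summed epithelial markers (1264 against 1801 CPM). HMOX1 rose 3.25-fold, and PRDX1 (0.80), TXN (0.43), FTH1 (0.42, and 0.22 after the length and GC correction) and GCLM (0.36, and 0.72 after it), genes of thiol reduction, iron storage and glutathione synthesis, rose as well. NQO1, a quinone reductase, went from 256 ± 13.1 to 79.9 ± 5.50 CPM, and ABCC3 (-2.02 ± 0.14), AKR1B10 (-1.58 ± 0.15) and AKR1C3 (-1.66), whose reads can be shared with close paralogs, were among 10 of 25 that fell. 17 passed adjusted over the list alone, and the list was not called (median -0.19, camera adjusted p = 0.220). Its median was -0.11 without control replicate 3 and -0.10 after the length and GC correction. In the interferon-stimulated list CMPK2 (1.93), EPSTI1 (1.06), IFI35 (1.14 ± 0.15), IFI6 (0.73) and OAS3 (0.66) rose, whereas PARP14 (-2.11 ± 0.21), MX1 (-1.49), OAS1 (-1.41 ± 0.27) and IFI27 (-1.16 ± 0.14) fell, out of 31, with 9 adjusted over the list alone (camera adjusted p = 0.572). Of 15 genes of MHC class I presentation, TAP1 (0.44) rose and the immunoproteasome genes PSMB8 (-1.10) and PSMB9 (-1.19) fell, with 3 adjusted over the list alone (camera adjusted p = 0.667). In the heat shock list HSPA8 (628 ± 36.9 to 1077 ± 21.5 CPM), HSPA1B, DNAJB1 and DNAJA1 rose and HSPA4L fell (-0.77, -0.25 after the correction and -0.51 without control replicate 3) out of 14, with 6 adjusted over the list alone (camera adjusted p = 0.0863; 0.0116 without control replicate 3 and 0.0476 without GPT1 replicate 1). Without GPT1 replicate 1 or 3, TAP1 and HSPA4L did not pass (edgeR adjusted p up to 0.0953 and 0.0557). The same held for IFI6 (0.0763), also without control replicate 1, and for MX1 (0.109), also without control replicate 2. It held for EPSTI1 (0.119), also without control replicate 1 or 3, and for GCLM (0.110), also without control replicate 1 or 2 or GPT1 replicate 2. CMPK2 did not pass without control replicate 1 or GPT1 replicate 1 (up to 0.0952), nor did EPSTI1 with DESeq2 (0.0590) or GCLM with the replicate number as a block (0.0673).

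Cell cycle and lipid lists gave no call with all 6 libraries and TMM factors. Of 36 G2/M genes, CCNB1 (0.67 ± 0.08), which encodes cyclin B1, CDC25B, AURKA, KIF2C and UBE2C rose, UBE2C (0.27) no longer after the length and GC correction (0.06, adjusted p = 0.436), and 6 fell, the kinetochore motor gene CENPE (-1.27 ± 0.22, and -0.72 after the correction) among them, with 13 adjusted over the list alone (camera adjusted p = 0.525). Without control replicate 1, GPT1 replicate 1 or GPT1 replicate 3, KIF2C did not pass (edgeR adjusted p up to 0.140). The same held for AURKA (0.182), also without control replicate 2, and for UBE2C (0.168), also without control replicate 3. CDC25B did not pass without GPT1 replicate 3 (0.0528). With the replicate number as a block AURKA, KIF2C and UBE2C did not pass (0.0725, 0.105 and 0.0963), nor KIF2C without a filter (0.0629). Of 38 DNA replication genes 11 changed, and 13 adjusted over the list alone (camera adjusted p = 0.0591; 0.0378 without control replicate 2, 0.0372 without GPT1 replicate 2 and 0.0389 with upper quartile factors). In the glycolysis list 6 of 23 fell, SLC2A1 among them, and 6 adjusted over the list alone (camera adjusted p = 0.476). Changed genes numbered 7 of 38 in the citric acid cycle list, 7 of 23 in cholesterol synthesis, 7 of 22 in fatty acid and triglyceride synthesis and 6 of 22 among endoplasmic reticulum chaperones. They numbered 7, 7, 7 and 7 adjusted over the list alone, with camera adjusted p of 0.901, 0.304, 0.525 and 0.572. Of 29 ribosome biogenesis and MYC target genes 9 changed, and 9 adjusted over the list alone (camera adjusted p = 0.378). In all, 15 of 34 tested lists were called with the preset correlation, 4 higher and 11 lower. With a correlation estimated per list, 0 were called by camera and 7 had an unadjusted p under 0.05. The rotation test fry, which does not compare a list with other genes, called 17 lists in one direction and 33 in either.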

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

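The correction for transcript length and GC content, and the settings of each list's median, were chosen after the data were seen, and the others before the data were examined. GPT stayed past the threshold with a log2 fold change of 13.19 to 13.86 under every setting run. The count of changed genes stayed within 1.5 times 4430 under other scaling factors (4303 to 4529), DESeq2 (4500), limma voom (4416), GPT left out (4429) and other filters (3148 to 5394), where fewer genes tested at a mean of 5 CPM left 1694 lower. A test against a 1.2-fold change called 1424 genes (527 higher, 897 lower), and an adjusted p of 0.01 called 1172 (491 higher, 681 lower), both by their construction. Correction for length and GC content called 6063 genes, 3286 of them higher, and shared 3672 of the 4430 calls, all in the same direction. Leaving out 1 library gave 1443 to 4907 genes, 613 to 1970 higher and 830 to 2937 lower. The lowest counts came without GPT1 replicate 3 (1443), GPT1 replicate 1 (1586) and control replicate 1 (2565), whereas 3981 genes passed without the shallowest library, control replicate 3. The cause was not tested beyond the loss of a sample. The deviations showed no pairing by replicate number, as those of same-numbered libraries correlated at 0.14, -0.28 and -0.08, and not every library correlated best with its own number. Each library's trend with length and GC content enters these correlations, so they do not exclude a pairing. With the number as a block 3886 genes passed (1416 higher, 2470 lower), and 15 lists were called. The 15 list calls became 0 with an estimated correlation between genes (the cause was not tested), 18 with camera on count residuals, 11 at an adjusted p of 0.01, 14 with the correction, and 13 to 16 without 1 library. Filters also ended calls, at a mean of 5 CPM (10 lists called, the enterocyte and goblet lists being too short to test) those of the NF-kB (adjusted p = 0.376, median -0.02), TGF-beta (0.245, median -0.09) and neural and kidney-line lists (0.0593, median -0.13), and at a CPM of 1 in 3 libraries those of the NF-kB (0.0520) and intestinal stem cell lists (0.0567), and with no filter that of the neural and kidney-line list (0.132, median -0.14), where the mesenchymal median was -0.19, by camera with Benjamini-Hochberg adjustment. No called list turned its direction. Of the 142 genes named beside GPT, none reversed a call, 37 lost theirs without at least 1 library, 12 with the replicate number as a block, 5 with another scaling factor, filter or DESeq2, 38 against a 1.2-fold change and 36 at an adjusted p of 0.01, and the 20 genes with the largest rises and falls kept theirs under every setting run. GPT2 passed with the length and GC correction (log2 fold change 0.20, adjusted p = 0.0198, edgeR), and PPAT, BCL2, MTR and UBE2C no longer passed (adjusted p = 0.984, 0.0805, 0.106 and 0.436). At these depths the simulated test missed many 1.5-fold changes, so genes that did not pass are not shown to be unchanged.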

Other observations

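Tests of the ribosomal and histone lists, of a smaller share of epithelial cells and of the identity of the cells were chosen after the results were seen, as was the selection of abundant genes. Tests of the oxidative phosphorylation and epithelial genes against length and GC content rest on a correction also added after the data were seen. Among genes with a mean of at least 100 CPM, from which GPT and XIST were left out by name, falls reached well beyond the lists. RHOB, a small GTPase gene, fell from 2193 to 1184 CPM, IRS4, an insulin receptor substrate, from 813 to 404 CPM, PLAT, the tissue plasminogen activator, from 559.5 to 286 CPM, and the atypical cadherin gene FAT1 from 163 to 77.7 CPM. Rises in that class included SRSF3, from 214 to 390.4 CPM, HNRNPM from 282 to 458 CPM and RBM3 from 202 to 330.4 CPM, and ATP6V0B, a subunit of the vacuolar proton pump, from 133 to 236 CPM. Each passed the edgeR test with Benjamini-Hochberg adjustment, with log2 fold changes of -0.89, -1.01, -0.97 and -1.07 for the falls and 0.86, 0.70, 0.71 and 0.82 for the rises, and all 3 libraries of a group on one side.

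Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many changed genes as the real one. It was the real split, with 4430 genes, and the highest of the other splits gave 0 by the edgeR test, with at most 1822 genes at an unadjusted p under 0.05. With 10 splits a share under 0.05 is out of reach. Every other split mixed libraries of both groups, so the group difference widened the spread within its groups and few calls were likely beforehand. The 0 therefore does not tell whether the real split arose by chance.

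The nuclear oxidative phosphorylation, ribosomal protein and histone lists were higher in the GPT1 libraries, in which short and GC-rich transcripts were higher in general. If that trend were the whole cause, the lists should return to about 0 once it is removed. The oxidative phosphorylation list kept a median of 0.27 (quartiles 0.09 to 0.51, camera adjusted p = 8.9e-07), against 0.33 before, and the histone list kept 0.46 (camera adjusted p = 0.0053). The correction used each gene's longest transcript, which need not be the expressed one. Part of the trend may therefore remain, and these medians do not decide whether it was the whole cause. The ribosomal list went from 0.15 (SD 0.19) to 0.084 (SD 0.23) and lost its call, with 8 members lower and 20 higher after the correction. Why the call ended was not tested further, and the trend may account for that list. The oxidative phosphorylation median stood 0.348 above that of all genes under 3 other scalings, but a scaling factor shifts all genes alike, so this does not test the scaling. An effect of GPT1 on the oxidative phosphorylation and histone lists stays open as a hypothesis, as does a remainder of the trend. With an estimated correlation between genes neither list was called (camera adjusted p = 0.417 and 0.240 after correction).

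Epithelial and intestinal genes were lower in the GPT1 libraries, with 30 of 51 measured genes of 3 lists down and a median of -1.76 among these. After removal of the trend with length and GC content 96.7% of the 30 still passed, a weak test because these genes were picked by their falls. The trend was smaller than the falls, with median log2 fold changes of -0.40 and -0.31 among genes of lowest GC content and longest transcripts. After its removal the median of the 30 was -1.78, which argues against the trend for these genes. A smaller share of colorectal epithelial cells in the GPT1 samples could lower them together, and 0 of the 51 rose (edgeR; 0 also at an unadjusted p under 0.05, with DESeq2 and with limma voom). With the length and GC correction 1 gene of the epithelial junction and keratin list rose. The falls were uneven, with an SD of 0.72 against a median standard error of 0.18, which 1 common factor would not give unless other cells supply part of these transcripts. Among the 19 genes that fell by over 1.5, around a median of -2.08, the SD was 0.35 against a median standard error of 0.20. Picking genes by the size of their fall narrows that spread. A smaller share would also raise the markers of other cell types alike, though by little if the lost share was small. The summed fibroblast and neural and kidney-line markers moved apart by 1.06 ± 0.12 (SE) on the log2 scale, but NEFM and NEFL carried this, and without these 2 genes the difference was 0.15 ± 0.07. A smaller share and lower expression per cell, whether or not through GPT1, cannot be told apart, because other cells that carry some of these transcripts would make the falls uneven too and the design ties either to the groups.

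In the controls 23 of 28 measured genes of the epithelial junction and keratin list stood under 100 CPM, beside VIM (1023 CPM), IRS4 (813 CPM), NEFM (293 CPM) and NEFL (152 CPM). The highest control mean among EPCAM, CDH1 and KRT19 was 51.2 CPM, whereas KRT8 reached 529 CPM and KRT18 reached 261 CPM. Low EPCAM, CDH1 and KRT19 could mean that most of the RNA came from cells other than a colorectal epithelial line. The summed epithelial junction and keratin list was higher, at 1801 CPM against 516 CPM for the neural and kidney-line list. These sums cover 29 and 15 members, and KRT8 and KRT18 made up much of the first, so they do not decide it. CDX2, an intestinal gene at 41.7 CPM in the controls, did not fall with CDH1 and KRT19 (45.3 CPM in the GPT1 libraries). Its level therefore does not decide it either. The source of the RNA stays open, since no reference profile of HCT8 was used here.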
